A study of Sus scrofa with 6 samples.

How the data were processed

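Total RNA of 6 porcine samples was measured on 6 Affymetrix expression arrays, 1 array for each of 6 conditions. The conditions were native growth plate cartilage, native articular cartilage, and cultures of chondrocytes isolated from each cartilage, taken at day 10 and day 20. Per the labels, chondrocytes were released with collagenase and grown at 37 °C in 5% oxygen and 5% carbon dioxide in DMEM/Ham's F12 with serum. Per the labels, RNA was extracted with Trizol and RNeasy columns, and biotinylated cRNA was made from 100 ng of total RNA by the Two-Cycle protocol. Whether the arrays of a tissue came from the same animals, or from a pool of animals, is not stated.

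The deposited values are linear signal intensities per probe set, made with GCOS 1.4 per the submitters' processing notes. The scaling target and the settings of the expression algorithm are not stated. The mean signal with the top and bottom 2% of probe sets left out differed between the 6 arrays by a factor of at most 1.00005, so the values were taken as scaled globally to a common mean near 400.1 and were not normalized again. The median signals were 71.2, 71.5 and 67.5 for native, day 10 and day 20 growth plate arrays, and 59.5, 68.7 and 69.4 for the articular arrays. Between 58.6% and 61.0% of the probe sets of an array lay above the floor described next. The table holds no detection calls. The number of arrays limits the precision.

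Of 24123 probe sets, 124 control probe sets were left out. A floor was set at the 40th percentile of all signals of the 23999 others, which was a signal of 36.1. Signals below the floor were raised to it, and log2 was taken. The platform's annotation paired 10069 probe sets with a single gene symbol and 198 with several, and left 13732 unnamed. Of those with 1 symbol, 9961 had a current gene ID in the RefSeq table, which was used only for names. Unnamed probe sets and those with several symbols were left out. Each of the 6765 genes was represented by the probe set with the highest mean log2 signal over the 6 arrays, and 2261 genes had more than 1 probe set. Genes above the floor on fewer than 2 arrays were left out, which left 5598 genes.

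An additive linear model of tissue (growth plate or articular) and stage (native, day 10 or day 20) was fitted to all 6 arrays with limma 3.58.1 in R 4.3.3, with an intensity trend in the prior variance. The data.table package, version 1.17.8, read the files. No condition was replicated, so the only residual was the tissue-by-stage interaction, on 2 residual degrees of freedom, to which the prior added 3.78. The contrasts were growth plate minus articular, the mean of both culture days minus native, and day 20 minus day 10. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and a change of at least 2-fold. Pairs of single arrays were compared without a test, by a rule of at least 4-fold. Where the lower array or arrays lay at the floor, folds are lower bounds and are written "at least". Expected overlaps of tissue differences over stages, and of day differences over tissues, were computed as if the pairs were independent. For the culture response only the 2 tissues were taken as independent, and the observed count at both days within a tissue was kept. For native differences seen again in culture, the native pair was taken as independent of the observed count at both culture days. Correlations were taken across genes between differences that share no array.

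There were 21 gene lists and 9 lists of markers of other cell types, written from general knowledge of the tissues. For each list the median log2 change of its measured members was set against 10000 random lists of the same size matched on mean signal. The percentile describes these arrays and is not a test. No percentile was computed for lists with fewer than 5 measured members. Calls were also made with the Benjamini-Hochberg adjustment run over the list alone.

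The genes named were set by rule. They were the called genes of a comparison, or, where none was called, the 10 each way with the largest mean change among genes at least 2-fold apart in the same direction in every pair of arrays. For pairs of single arrays they were the 10 genes each way with the largest ratio. Up to 4 members of each list with the largest change were named, and the cartilage genes COL2A1, ACAN, SOX9, COL1A2, COL10A1, IHH and MMP13. The comparisons, model, thresholds, lists and naming rule were fixed before the data were examined. Genes named outside the rule are described as chosen after their values were seen.

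The alternatives were quantile normalization, median centring, a floor at the 25th or 60th percentile, a pseudocount in place of the floor, no filter, a filter requiring all 6 arrays above the floor, the mean of a gene's probe sets, every probe set as a feature, no intensity trend, size rules of 2-fold and 8-fold, other models of stage and tissue, a fit to the 4 cultured arrays, and leaving out each array in turn. A tissue-by-culture fit and the use of the fit to the cultured arrays for day 20 against day 10 were chosen after seeing the data.

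The fits were tested on simulated data with the spread of the fitted arrays, in which 67 genes per comparison were made 2-fold different, 67 were made 4-fold different and 66 were made 16-fold different. In the model of all 6 arrays, 79.1% of the genes made 4-fold different between tissues were called, 67.2% of those made 4-fold different in culture, and 49.3% of those made 4-fold different between days. At 2-fold the shares were 5.97%, 7.46% and 4.48%, and at 16-fold they were 100%, 98.5% and 90.9%. Of 5398 unchanged genes, 1 was called for tissue, 6 for culture and 8 for day. In the fit to the 4 cultured arrays, on 5473 genes, 97% of the 4-fold tissue differences and 98.5% of the 4-fold day differences were called, with 3 and 7 of 5273 unchanged genes called. No simulated array stood apart from the others. The noise was drawn independently for each array from the prior spread that the fit itself assumes, and no floor was applied. The shares therefore show how the fits do where their assumptions hold, not whether these hold for the real arrays.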

Results

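Gene expression was measured in porcine growth plate cartilage, the cartilage that lengthens growing bones and mineralises, and in porcine articular cartilage, which covers the joint surface. Each cartilage was measured as native tissue and as a culture of its isolated chondrocytes at day 10 and day 20 of differentiation, with 1 array per condition and 6 arrays in total. The highest signal of an array lay between 19960 and 27967, and 5598 genes were compared. Signals are given in the order native, day 10, day 20. There were no replicates. The p-values, from limma, set each difference only against how far the arrays departed from a sum of a tissue effect and a stage effect, and differences between single arrays had no replicate check.

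The first comparison asked which genes set growth plate chondrocytes apart from articular chondrocytes at every stage. Genes of cartilage mineralisation led it. COL10A1, which encodes the collagen of hypertrophic cartilage, had signals of 1114, 2375 and 1655 in growth plate and 4.51, 26.4 and 30.8 in articular samples. It was at least 45.3-fold higher in growth plate on average over the stages, with a log2 difference of at least 5.50 ± 0.32 (SE) and a limma adjusted p of 0.0193. ALPL, the alkaline phosphatase that frees phosphate for mineral, had signals of 1522, 3057 and 2287 against 24.2, 29.9 and 90.9. It was at least 42.1-fold higher in native tissue, at least 84.6-fold at day 10 and 25.1-fold at day 20, with a log2 difference of at least 5.48 ± 0.39 and a limma adjusted p of 0.0298. GEM, a small GTPase of cytoskeleton and calcium channel control, was lower in growth plate, at 1333, 238 and 204 against 6431, 1366 and 1279. Its log2 difference was -2.48 ± 0.20, a limma adjusted p of 0.0406. GEM and ALPL each differed in the same direction in 3 of 3 pairs of arrays. So did COL10A1, but it passed the filter only through growth plate arrays, which fixed its direction. Articular signals under the floor were set equal to it, which holds for every one of COL10A1 and the native and day 10 ones of ALPL. The spread of those signals below the floor does not enter the standard errors and p-values.

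These 3 were the only genes called among 5598, 2 higher and 1 lower in growth plate, and 598 genes (10.7%) had an unadjusted p under 0.05. The calls depended on the processing. None was made with no filter, with a filter on all 6 arrays, which leaves out COL10A1 and ALPL, or with every probe set as a feature, and COL10A1 alone was called without the intensity trend or with the mean of a gene's probe sets. Far more genes kept a difference across the pairs. In all 3 pairs, 31 genes were at least 2-fold higher and 18 at least 2-fold lower in growth plate, where 0.699 and 0.690 would be expected of independent pairs. How many genes were called depended on which arrays were fitted. In a limma fit to the 4 cultured arrays alone, 67 genes were called higher and 85 lower in growth plate cultures. That fit had 1 residual degree of freedom, to which the prior, drawn from all genes, added 12.3. Fits that leave out either native array draw the tissue difference from the same 4 arrays and are no separate check.

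The hypertrophic and mineralising chondrocyte genes were higher in growth plate as a group. All 11 measured members had positive log2 differences, that of COL10A1 being fixed by the filter. Their median of 1.57 lay at percentile 100 of matched random lists. Of the 11, 7 were at least 2-fold higher, 5 of them in all 3 pairs, and none was 2-fold lower. Over all genes 2 were called, and adjusted over the list alone 7 were. IBSP, a bone matrix protein that binds mineral, had signals of 10642, 14034 and 15675 in growth plate against 53.2, 309 and 5958 in articular samples. The ratio therefore went from 200-fold in native tissue to 45.5-fold at day 10 and 2.63-fold at day 20. PTH1R, the receptor that holds back hypertrophy, had signals of 3431, 4864 and 3352 against 136, 503 and 1118. MMP13, a collagenase of mineralising cartilage, had signals of 91.2, 299.7 and 513 against 39.8, 27.0 and 30.5. IHH, a signal made by prehypertrophic cells, had signals of 118, 448 and 82.1 against 69.4, 49.9 and 48.0.

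**Figure D1:**
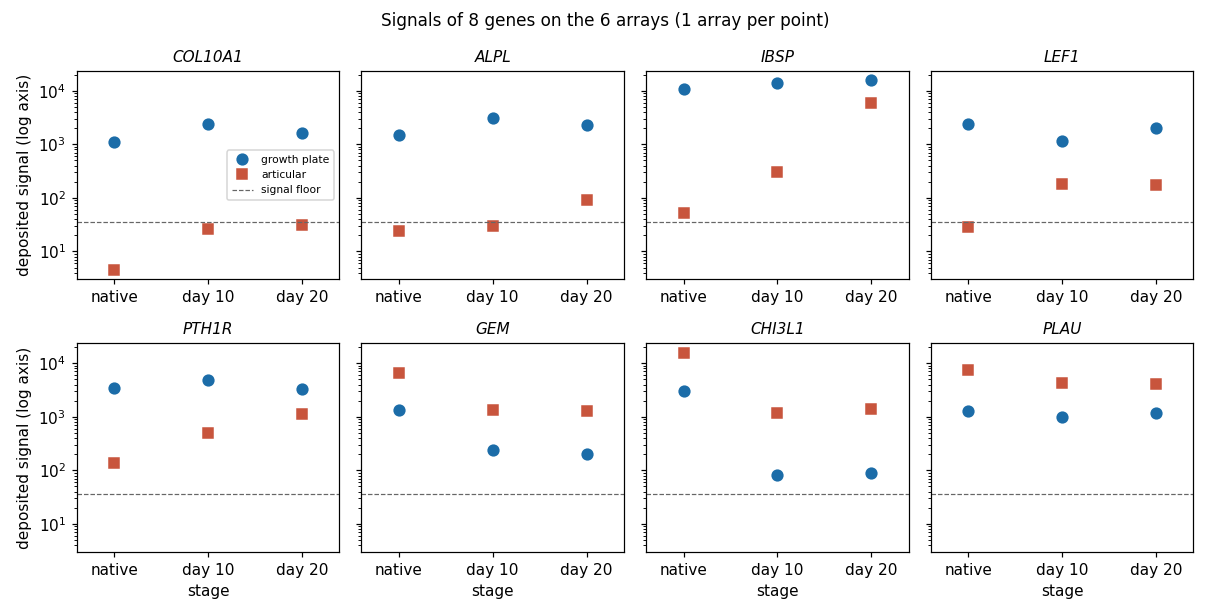
Deposited signal on a log axis of 8 genes of the tissue comparison at native, day 10 and day 20, with 1 array per point, growth plate as circles, articular as squares and the floor dashed. COL10A1 lay between 1114 and 2375 on the growth plate arrays and at or below 30.8, under the floor, on the articular arrays.

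Several signalling and protease genes also differed at every stage without being called. LEF1, a transcription factor of WNT signalling, had signals of 2408, 1140 and 2031 in growth plate against 28.0, 179 and 176 in articular samples. TGFB2 had signals of 3066, 1448 and 2526 against 749, 537 and 801, a log2 difference of 1.71 ± 0.20. Its list, BMP and TGF-beta signalling, had a median of 0.47 over 11 measured genes, percentile 99.9, with 4 genes at least 2-fold higher, none 2-fold lower, 0 called and 1 called when adjusted over the list alone. A2M, an inhibitor of matrix proteases, had signals of 717, 669 and 389 against 11.7, 40.9 and 67.1, but its other probe set, at or near the floor, had a log2 difference of 0.14 where the one used had at least 3.63. PLAU, the urokinase protease, was lower in growth plate, at 1284, 979 and 1172 against 7595, 4205 and 4093, with a log2 difference of -2.16 ± 0.20 and a limma adjusted p of 0.0604. CHI3L1, a secreted glycoprotein of stressed and differentiating chondrocytes, was also lower, at 2984, 81.6 and 89.3 against 15448, 1193 and 1395, with a limma adjusted p of 0.0907. The 14 measured matrix proteases and inhibitors had a median of 0.17, percentile 98.2, with 3 genes at least 2-fold higher and 2 at least 2-fold lower; 0 were called, and 2 higher and 1 lower were called when adjusted over the list alone.

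Genes of the articular surface went both ways. Over 10 measured members the median was 0.03, percentile 70.8, with 2 genes at least 2-fold higher and 2 at least 2-fold lower in growth plate. None was called over all genes, and 1 higher and 2 lower were called when adjusted over the list alone. ERG, a transcription factor of developing joints, was lower in growth plate, at 427, 258 and 388 against 781, 759 and 782. SFRP1, a WNT inhibitor, was lower too, at 201, 58.8 and 118 against 632, 453 and 179. GPX3, a secreted peroxidase, was higher in growth plate, at 119, 256 and 335 against 17.1, 13.3 and 88.5. PRG4, the joint lubricant, was not analysed here.

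The second comparison set native growth plate against native articular cartilage, 1 array against 1 array. In growth plate, 193 genes were at least 4-fold higher and 67 at least 4-fold lower. Among the genes of largest ratio, SLC2A5, a fructose transporter, had signals of 6221 and 63.5 in native growth plate and articular cartilage, a 98.0-fold difference. LEF1 was at least 66.6-fold higher, and FOXA2, a transcription factor of hypertrophic differentiation, was at least 34.4-fold higher. On the articular side ISG15, a ubiquitin-like protein induced by interferon, had a signal of 2032 against 51.8 and was 39.2-fold higher than in growth plate. HMGA1, a chromatin protein, had a signal of 9486 against 396. The interferon response list did not move with ISG15, since its 13 measured genes had a median of 0.12, percentile 76.6, with 3 at least 2-fold higher and 3 at least 2-fold lower.

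As groups, cell cycle genes and genes of BMP and TGF-beta signalling were higher in native growth plate than in native articular cartilage. The cell cycle list had a median log2 difference of 1.05 over 21 measured genes, percentile 100, with 12 at least 2-fold higher and 3 at least 2-fold lower. Those 3 were the replicative helicase genes MCM2, MCM4 and MCM5, at -1.94, -1.25 and -1.39. Their other probe sets had -1.73, 0 and -0.47, so only MCM2 was at least 2-fold lower on both of its probe sets. CCNB1, a mitotic cyclin, had signals of 3984 and 122, a 32.6-fold difference, and CDC20, an activator of mitotic exit, had signals of 1053 and 62.0. The BMP and TGF-beta signalling list had a median of 2.03, percentile 100, with 6 genes at least 2-fold higher and 1 at least 2-fold lower. ID1 and ID3, direct targets of BMP signalling, had native signals of 2959 against 131 and 2268 against 152. The WNT signalling list had a median of 1.09 over 7 genes, percentile 99.2. Relative to native tissue, the BMP and TGF-beta medians at day 10 and day 20 were 0.53 and 1.57 in articular samples. In growth plate samples they were -0.26 and -0.28. The WNT medians were 1.44 and 1.03 in articular and -0.42 and -0.25 in growth plate samples. These native differences therefore rest largely on the native articular array. Glycolysis and hypoxia genes had a median of 0.46 over 20 genes, percentile 99.8, led by ANKRD37, which was 33.9-fold higher in growth plate.

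Immediate early genes, and some inflammatory genes, were higher in native articular cartilage. Of 18 measured immediate early and heat shock genes, 9 were at least 2-fold lower in growth plate and 0 at least 2-fold higher, with a median of -1.003, percentile 0. ATF3, a stress-induced transcription factor, had signals of 426 in growth plate and 5789 in articular cartilage, and ZFP36, which shortens the life of cytokine mRNAs, had signals of 406 and 3778. Inflammatory mediators went both ways, with 8 positive and 9 negative differences, a median of -0.29 and percentile 5.06; 6 of 17 were at least 2-fold lower and 2 at least 2-fold higher in growth plate. LIF was at least 20.4-fold higher in articular cartilage, CXCL2 was 20.0-fold higher and CCL5 was at least 14.3-fold higher. The native articular array was also the least similar to the rest, with a mean correlation across genes of 0.890 to the other arrays, where the other 5 arrays had 0.930 to 0.939.

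The next question was whether differences between native tissues were seen again in culture. At day 10, 63 genes were at least 4-fold apart between the cultures, and at day 20 there were 62. At both days and in the same direction 18 were, 8 higher and 10 lower in growth plate, where 0.338 would be expected of independent days. Among the 8 were COL10A1, ALPL, LEF1, MMP13 and A2M. Among the 10 were CHI3L1, GEM and NFIA, along with TGFB3, a growth factor that went the other way in native tissue. TGFB3 had signals of 911, 486 and 610 in growth plate against 143, 2329 and 2794 in articular samples. Its other probe set, of signals near the floor, had a native log2 difference of -0.46 where the one used had 2.68, so the native direction rests on 1 probe set. CDO1, an enzyme of cysteine breakdown, changed sides in the same way, at 2135, 1091 and 771 against 647, 4835 and 5919. PTX3, a secreted pattern recognition protein, had culture signals of 80.2 and 162 in growth plate against 666 and 2766 in articular samples.

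Of the 193 genes at least 4-fold higher in native growth plate, 18 were at least 2-fold higher at both culture days. If the native pair were independent of the cultures, 1.72 would be expected, with the count at both culture days taken as observed. Of the 67 lower, 8 were at least 2-fold lower at both days, where 0.802 would be expected on the same assumption. Across the 5598 genes, which are not independent replicates, the tissue difference in native cartilage correlated with that at day 10 with Pearson's r of 0.245 and Spearman's rho of 0.160. With day 20 the values were 0.228 and 0.187. Between day 10 and day 20 they were 0.408 and 0.322. The hypertrophic list stayed apart in culture, with medians of 3.05 at day 10 and 1.396 at day 20, both at percentile 100. Several other lists that were far apart in native tissue lay closer in culture. At day 10 and day 20 the cell cycle medians were -0.29 and -0.17, the BMP and TGF-beta signalling medians 0.16 and -0.30, and the immediate early medians -0.07 and -0.22. The WNT signalling medians were 0.02 and 0.17. The glycolysis and hypoxia list lay at 0.02 at day 10 but at 0.40, percentile 100, at day 20. Some lists lay close in native tissue and apart at day 10 or at day 20 of culture, and only that day is given for them. The fibroblastic matrix median was 0.10 in native tissue and -0.80, percentile 0, at day 10, and the interferon response median was 0.12 in native tissue and -0.80, percentile 0, at day 20. CCNB1 had day 10 signals of 4175 in growth plate and 4877 in articular cultures, ID3 had 3185 and 3358, and ATF3 had 571 and 368.

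The third comparison asked how chondrocytes in culture differed from native cartilage in both tissues. Contractile cytoskeleton genes were higher as a group, and inflammatory genes were lower. TMEM158, a membrane protein induced by RAS signalling, had signals of 115, 447 and 5052 in growth plate and 3.84, 502 and 2575 in articular samples. Its log2 change was at least 4.34 (SE 0.41), since native articular cartilage lay under the floor, and its limma adjusted p of 0.0724, shared with CHI3L1, was the smallest of the comparison. PDLIM1, an adaptor of actin stress fibres, had signals of 197, 699 and 2566 in growth plate and 31.3, 1142 and 4139 in articular samples. Among genes lower in culture, CHI3L1 had a log2 change of -4.35 ± 0.38. MT-2B, a metallothionein, went from 2348 to 442 and 253 in growth plate and from 12162 to 862 and 343 in articular samples.

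With limma 0 genes were called in either direction, and 1083 genes (19.3%) had an unadjusted p under 0.05. At both days in both tissues 39 genes were at least 2-fold higher and 39 at least 2-fold lower in culture, where 7.82 and 5.68 would be expected of independent tissues. The articular samples differed more from their native tissue. At both days 547 genes were at least 2-fold higher and 289 lower in articular cultures, against 80 and 110 in growth plate cultures, and the articular counts rest on the native articular array. Without that array 97 genes were called higher and 119 lower in culture, and without native growth plate cartilage 753 and 412 were. In each of these fits native tissue is 1 array, assumed to vary like the cultured ones, and the larger counts rest on the native articular array alone. Across genes the response of growth plate and articular chondrocytes correlated with Pearson's r of 0.396 and Spearman's rho of 0.388 at day 10, and with 0.406 and 0.320 at day 20.

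Inflammatory mediators had a median change of -1.25 over 17 measured genes, percentile 0. By day 10 and day 20 the medians were -2.01 and -0.31 in growth plate and -1.42 and -0.54 in articular samples, so that they were lowest at day 10. Of these, 9 were at least 2-fold lower and 1 at least 2-fold higher, and 5 were lower in all 4 pairs. Over all genes 0 were called, and adjusted over the list alone 6 lower and 1 higher were. CXCL8, a neutrophil chemokine, went from 550 to 49.8 and 109 in growth plate and from 3084 to 34.8 and 91.2 in articular samples. NFKBIA, an inhibitor and target of NF-kappa B, went from 1849 to 383 and 387 and from 10273 to 595 and 797. CXCL14 was the member that was higher, going from 89.0 to 253 and 4873 in growth plate and from 1.64 to 490 and 360 in articular samples. Immediate early and heat shock genes had a median of -0.60, percentile 0, with 7 of 18 at least 2-fold lower and 2 at least 2-fold higher; 0 were called over all genes, and 1 each way was called when adjusted over the list alone. By tissue their medians were -1.45 and -0.56 at day 10 and day 20 in articular samples, and -0.28 and 0.09 in growth plate samples.

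Contractile cytoskeleton genes had a median of 0.79 over 18 measured genes, percentile 100, with 6 at least 2-fold higher, 2 of them in all 4 pairs, and 0 at least 2-fold lower. None was called over all genes, and 5 were when adjusted over the list alone. CNN1, a regulator of smooth muscle contraction, went from 42.5 to 157 and 561 in growth plate and from 37.8 to 188 and 1472 in articular samples. TAGLN, an actin cross-linker, went from 758 to 3483 and 6398 and from 2365 to 5574 and 7903. Of 12 skeletal muscle markers on the array, 3 lay above the floor on at least 2 arrays and were measured. These 3 were all higher in culture, with a median of 1.88, and 2 were at least 2-fold higher. Over all genes 0 were called, and 2 were when adjusted over the list alone. DES, a filament protein of muscle, went from 29.9 to 127 and 326 in growth plate and from 10.1 to 247 and 291 in articular samples. Both DES and MYH7, another of the 3, lay at or under the floor on both native arrays. They passed the filter only through cultured arrays, which fixed their direction, so their being higher is no result. MYL1, a myosin light chain, went from 75.1 to 279.7 and 126 and from 20.1 to 256 and 151. Fibroblastic matrix genes had a median of 0.38 over 17 genes, percentile 99.6, with 6 at least 2-fold higher and 1 at least 2-fold lower; 0 were called, and 1 each way was called when adjusted over the list alone. By tissue the fibroblastic medians were -0.58 and 0.25 at day 10 and day 20 in growth plate, and 0.50 and 1.45 in articular samples. VCAN, a large proteoglycan of fibrous matrix, went from 84.8 to 136 and 1312 in growth plate and from 92.0 to 457 and 2489 in articular samples. COL1A2 went from 432 to 381 and 2343 and from 146 to 585 and 838, with a log2 change of 1.70 on this probe set and 0.95 on its other, and COL1A1 was not analysed here.

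Genes of the cartilage matrix moved little as a group. Their median culture change was -0.16 over 8 measured genes, percentile 20.8, with 1 at least 2-fold higher and 0 at least 2-fold lower; 0 were called, also when adjusted over the list alone. COL2A1, the main collagen of hyaline cartilage, had signals of 1615, 1361 and 1603 in growth plate and 2929, 1164 and 1689 in articular samples. ACAN, the main proteoglycan, had signals of 14874, 12466 and 6596 and of 15883, 10781 and 10267. HAPLN1, which links proteoglycan to hyaluronan, had a log2 change of -0.05 ± 0.16. It was chosen outside the naming rule, after its value was seen. COMP, another member, changed more, by 0.54 on the probe set used and 0.19 on its other. The member that was at least 2-fold higher was LUM, a collagen-binding proteoglycan, at 956, 780 and 10749 and at 15.5, 1498 and 2784. SOX9, the transcription factor of cartilage, had signals of 175, 125 and 118 in growth plate and 982, 81.0 and 76.8 in articular samples.

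The fourth comparison asked what differed between day 20 and day 10 of culture. Cell division genes were lower and genes of low oxygen and of fibrous matrix higher at day 20, in both tissues. PCNA, the clamp of the replication fork, went from 1697 to 409 in growth plate and from 3319 to 585 in articular cultures between the days. ENO2, a glycolytic enzyme, went from 22.0 to 1391 and from 6.76 to 816, at least 38.5-fold and at least 22.6-fold higher. PTHLH, the ligand that delays hypertrophy, went from 28.7 to 856 and from 95.4 to 756, and SCARA5, a ferritin receptor of mesenchymal cells, from 30.4 to 893 and from 57.7 to 568. POLE2, a subunit of DNA polymerase, went from 259 to 61.7 and from 430 to 43.0.

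**Figure D2:**
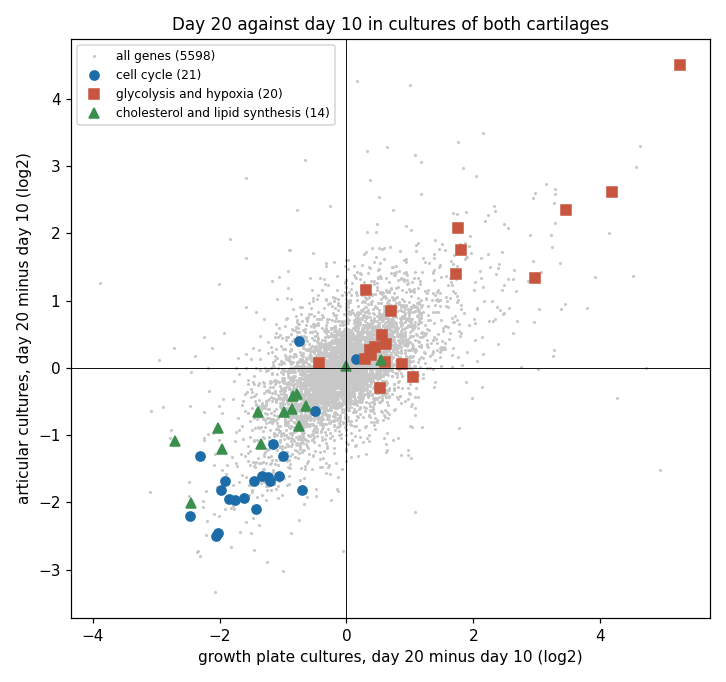
Log2 change from day 10 to day 20 for 5598 genes, growth plate cultures on the x axis and articular cultures on the y axis, with cell cycle genes as circles, glycolysis and hypoxia genes as squares and cholesterol and lipid synthesis genes as triangles. Most cell cycle genes, whose median fitted change was -1.57, lay at the lower left.

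With limma and all 6 arrays 0 genes were called, the smallest adjusted p was 0.148, and 820 genes (14.6%) had an unadjusted p under 0.05. In both tissues 139 genes were at least 2-fold higher and 160 at least 2-fold lower at day 20, where 21.4 and 21.9 would be expected of independent tissues. The limma fit to the 4 cultured arrays, used for this comparison only after the data had been seen, called 258 genes higher and 251 lower on 1 residual degree of freedom. Fits that leave out either native array draw this difference from the same 4 arrays. Leaving out 1 cultured array from all 6 gave between 0 and 2 higher and between 0 and 1 lower. Across genes the change from day 10 to day 20 correlated between tissues with Pearson's r of 0.598 and Spearman's rho of 0.572, the highest of the 6 pairs of differences compared.

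The cell cycle list had a median change of -1.57 over 21 measured genes, percentile 0, and 20 of the 21 were negative. Of these, 18 were at least 2-fold lower, 17 of them in both tissues. None was called with all 6 arrays, 11 were when adjusted over the list alone, and 18 were in the fit to the cultured arrays. RRM2, which makes deoxynucleotides, went from 3051 to 754 in growth plate and from 3734 to 678 in articular cultures. Its limma adjusted p was 3.55e-05 in the fit to the cultured arrays, most of whose degrees of freedom came from the prior. MCM3, part of the replicative helicase, went from 416 to 75.2 and from 620 to 134. The member that was not lower was TYMS, with a log2 change of 0.14. Against native tissue the list stood at 0.21 at day 10 and -1.02 at day 20 in growth plate, and at 1.93 and 0.25 in articular samples, whose native array had low cell cycle signals. Cholesterol and lipid synthesis genes were lower as well, with a median of -0.81 over 14 genes, percentile 0, and 6 at least 2-fold lower. None was called, 5 were when adjusted over the list alone, and 6 were in the fit to the cultured arrays. FDPS, an enzyme of the mevalonate pathway, went from 2122 to 390 and from 2137 to 533.

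Glycolysis and hypoxia genes had a median of 0.51 over 20 measured genes, percentile 100, and 7 were at least 2-fold higher, all of them in both tissues. None was called with all 6 arrays, 4 were when adjusted over the list alone, and 7 were in the fit to the cultured arrays. CA9, a carbonic anhydrase induced by low oxygen, went from 119 to 1309 in growth plate and from 195 to 988 in articular cultures. VEGFA, the growth factor of blood vessels, had signals of 5588, 1715 and 5792 and of 5032, 1282 and 5440, so that day 20 lay near native tissue; its day change was 1.92 on the probe set used, and 1.79 and 0.26 on its others. Fibroblastic matrix genes had a median of 0.92, percentile 100, with 8 of 17 at least 2-fold higher, 3 of them in both tissues. None was called with all 6 arrays, 2 were when adjusted over the list alone, and 8 were in the fit to the cultured arrays. POSTN, a matrix protein of fibrous tissue, went from 12.9 to 161 and from 84.7 to 949. Inflammatory mediators had a median of 0.44, percentile 99.95, with 6 of 17 at least 2-fold higher; 0 were called, and 3 were when adjusted over the list alone. C1S, a protease of the complement system, went from 246 to 2321 and from 696 to 2425.

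**Figure D3:**
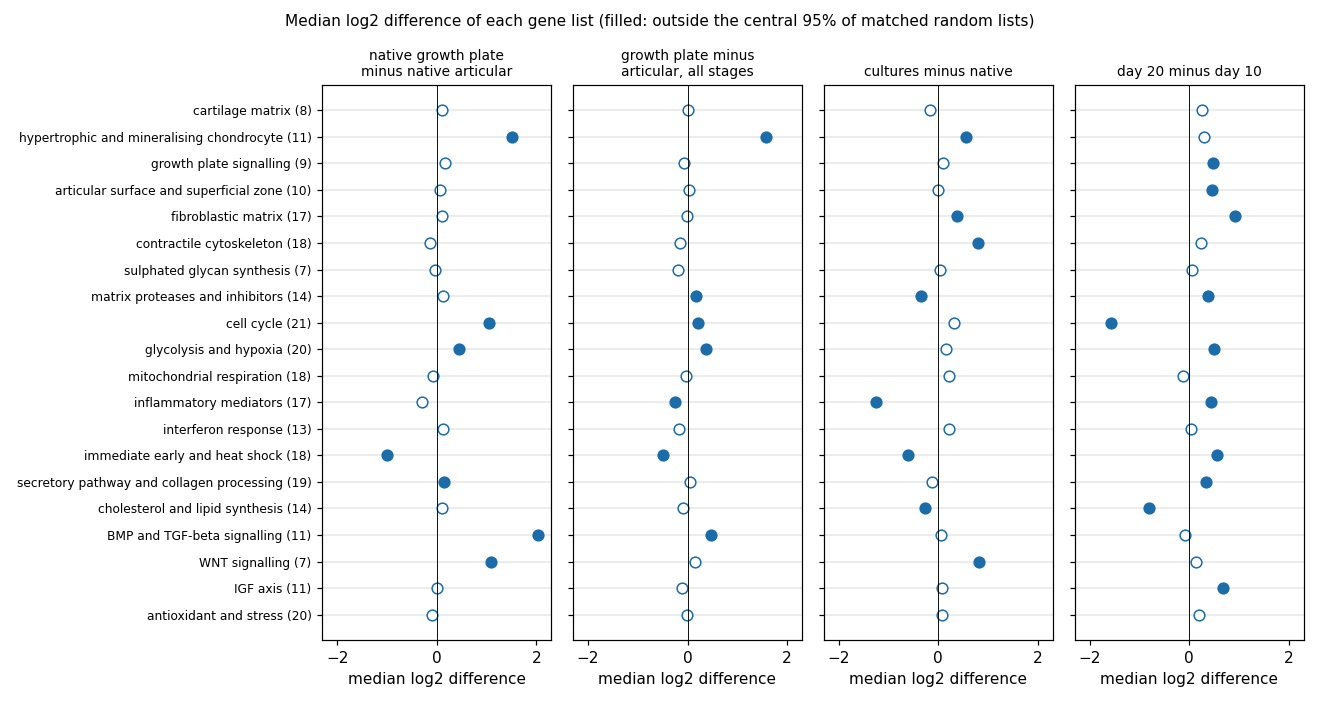
Median log2 difference of each list with at least 5 measured genes, their number in brackets, in the native pair and in the tissue, culture and day comparisons; filled points lay outside the central range, given in the title, of 10000 matched random lists. The hypertrophic list stood at 1.57 for tissue, the inflammatory list at -1.25 for culture and the cell cycle list at -1.57 for day.

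Markers of other cells were measured only where they lay above the floor on at least 2 arrays. Of those on the array this kept 1 of 5 for erythroid cells, 1 of 16 for myeloid cells and 1 of 9 for lymphocytes. For endothelium and pericytes it kept 7 of 13, and for osteoblasts and osteocytes 7 of 9. HBB, a haemoglobin chain, had signals of 234, 426 and 289 in growth plate and 398, 610 and 342 in articular samples. S100A9 and JCHAIN, the only measured markers of myeloid cells and lymphocytes, had signals of at most 49.4 and 49.1. PECAM1, of endothelium, had signals of 67.2, 52.9 and 52.6 in growth plate and 277, 118 and 65.6 in articular samples, a log2 difference of -1.17 on this probe set and -0.17 on its other, which lay near the floor. The endothelium and pericyte list had a tissue median of -0.17 over 7 genes, percentile 17.1. Between the days its median was 0.31, percentile 90.8, with 2 genes at least 2-fold higher at day 20 in both tissues, 0 called and 2 called when adjusted over the list alone. They were CLDN5, of endothelial junctions, and PDGFRB, a receptor of pericytes and fibroblasts, which went from 305 to 941 in growth plate and from 839 to 2117 in articular cultures. The rise of PDGFRB rests on 1 probe set, with a log2 change between the days of 1.48 on it and -0.14 on its other. The osteoblast and osteocyte list had a tissue median of 0.81 over 7 genes, percentile 99.98, and it shares ALPL and IBSP with the hypertrophic list. CTSK, a protease of osteoclasts that chondrocytes can make, had signals of 14768, 6548 and 7793 in growth plate and 17802, 5803 and 8225 in articular samples.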

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

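The tests of the native articular array, of the cell cycle genes and of ALPL and IBSP were chosen only after the results were seen, and the bounds of those on an immediate early response and on 3' bias were reworded after their outcomes were known; the count over splits of the arrays was planned.

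In 9 genes the response to culture went opposite ways in the 2 tissues, at least 2-fold lower at both days in growth plate and at least 2-fold higher at both days in articular samples. These genes were picked by direction alone after their values were seen, and the difference between the tissues was not tested by that choice. As growth plate response minus articular response in log2, the values were -4.69 for NEK2, -4.59 for F2R, -4.13 for SEPT4, -3.69 for EPB41L1, -3.41 for FST, -2.92 for IGFBP6 and -2.68 for STK17A. ARHGDIB and PPARD lay under the floor on the native articular array, so their values of -3.50 and -3.01 are set by the floor, and the differences were at least of that size. F2R, the thrombin receptor, had signals of 358, 71.5 and 51.4 in growth plate and 58.4, 241 and 235 in articular samples. If the tissues were independent, 10.8 such genes would be expected, and the opposite pattern was seen in 0 genes where 4.13 would be expected. A limma tissue-by-culture fit, also chosen after the data were seen, tested the difference over all 5598 genes and called 0, with 471 genes at an unadjusted p under 0.05. All 9 genes had lower signals in native articular than in native growth plate cartilage, which the way they were picked largely fixed.

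The native articular array stood apart from the other 5. Its pair with native growth plate had 260 genes at least 4-fold apart, 4.13 times the 63 of the larger cultured pair, and on this array 33 genes lay at least 4-fold above and 63 at least 4-fold below all others, where other arrays had at most 7 and 2. After quantile normalization, which makes the distributions equal, the ratio was 3.60 (227 genes against 63), which argues against a difference in signal distribution as the whole cause. Of the 3 ratios of 3' to 5' signal that degraded RNA would raise, 1 was higher than on every other array: GAPDH had 1.52 against a next highest of 1.49, actin had 4.28 within a range of 3.27 to 8.75, and EF1A had 1.07, the lowest of 6, so that the ratios disagree and RNA degradation stays open. An immediate early and inflammatory response in the native articular sample, during dissection or in the animal, may explain part of it. To test it, 72 genes were taken out. They were the measured members of the immediate early, inflammatory and interferon lists, and the 33 genes at least 4-fold above all others on this array. Without them 224 genes were at least 4-fold apart in the native pair, 3.56 times the 63 of the larger cultured pair. No genes were taken out of the cultured pair. Since a response could also lower genes, this explanation stays open, as do a difference between the tissues or between animals, which were not tested.

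Cell cycle genes were lower at day 20 than at day 10 in both tissues. Their median change in growth plate and articular cultures was -1.42 and -1.68 as deposited, -1.39 and -1.68 after quantile normalization, and -1.34 and -1.66 after median centring, which argues against a difference in scaling. A 3' bias of the day 20 arrays cannot be told apart from the change, because the ratios disagree: only 1 of the 3 fell in both tissues, GAPDH, from 1.49 to 0.995 and from 1.44 to 1.15, while actin went from 3.27 to 5.55 and from 4.58 to 8.75 and EF1A from 1.25 to 1.31 and from 1.45 to 1.51. Slower division in older, denser cultures is possibly the cause, and no count of cells was used here to test it.

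ALPL and IBSP were higher on every growth plate array. Osteoblasts carried over with growth plate cartilage might raise both, and they would bring COL1A2 and BGLAP as well. The log2 difference of COL1A2 between growth plate and articular arrays was 1.56 in native tissue, -0.62 at day 10 and 1.48 at day 20, and that of BGLAP was 0.26, -0.84 and 0, with BGLAP near the floor. These values rest on 1 probe set of COL1A2: its other probe set, under the floor on both native arrays, gave no native difference and had a fitted tissue difference of 0.08, against 0.81 for the one used. Osteoblasts cannot be told apart from mineralising chondrocytes as the source, since the values of COL1A2 differ between stages and between probe sets.

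The 3 genes called between tissues were set against other splits of the 6 arrays into 3 and 3. The real split gave 3 genes and the highest of the others gave 0, so that 1 of 10 splits gave as many, and 10 splits are too few for a share under 0.05. Stage was kept in every fit. A split holding both arrays of a stage therefore drew its difference from 1 pair of arrays, against 3 pairs in the real split. Such splits could call genes less readily.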

How the results depend on the processing

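The tissue-by-culture fit and the use of the cultured arrays alone for day 20 against day 10 were chosen only after the results were seen; the other alternatives were planned. No paired analysis was possible because the labels tie no arrays to the same animals; the fits with a stage term compare the tissues within each stage.

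Counts of called genes depended most on the native arrays. Leaving out each array in turn gave 1 to 753 genes higher and 6 to 412 lower in culture, 2 to 65 higher and 0 to 82 lower in growth plate, and 0 to 257 higher and 0 to 250 lower at day 20. Each such fit keeps 1 residual degree of freedom, and conditions are assumed to vary alike. Without a native array, tissue and day differences come from the 4 cultured arrays by construction, so these are no separate check, and native tissue is 1 array in the culture contrast. Growth plate and articular counts without native articular cartilage were 65 and 82, and without native growth plate cartilage 58 and 75; without these arrays the culture counts were 97 and 119, and 753 and 412, and the day counts 257 and 250, and 251 and 248. Without the growth plate day 20 array the counts were 54 and 55 for culture, 23 and 4 for tissue, and 1 and 0 for day. Without the articular day 20 array they were 15 and 11, 22 and 4, and 2 and 1. Without the growth plate day 10 array they were 13 and 8, 2 and 0, and 0 and 0, and without the articular day 10 array 1 and 6, 3 and 0, and 0 and 0. The cultured arrays only gave 67 higher and 85 lower for tissue and 258 and 251 for day.

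For tissue, genes higher and lower in growth plate numbered 4 and 2 under quantile normalization, 1 and 0 with eBayes without trend, 1 and 0 with the mean of a gene's probe sets, and 4 and 0 without the stage term. They numbered 0 and 0 with no filter, above the floor on all 6 arrays, and with every probe set as a feature. Lower genes numbered 2 under median centring and a floor at the 25th percentile, and 3 with a floor at the 60th percentile and with a pseudocount. For culture, median centring gave 1 higher and 4 lower, the 60th percentile floor 2 and 3, the pseudocount 4 lower, above the floor on all 6 arrays 3 lower, and every probe set 1 higher. That last feature was the other probe set of ACTG2, a contractile cytoskeleton gene, with a log2 change of 4.98 against 1.21 on the one used. The cause of these shifts in the counts was not tested. Over the settings of normalization, floor, filter, probe sets and trend and the fits without 1 array, COL10A1 was called in 13 of 15 (log2 3.59 to 6.14, adjusted p 2.65e-07 to 0.547), ALPL in 11 of 15 (4.02 to 5.90, 1.77e-06 to 0.587) and GEM in 9 of 16 (-2.59 to -2.35, 5.37e-05 to 0.547), each in its direction throughout; the cultured arrays only gave adjusted p of 1.51e-07, 1.35e-06 and 4.46e-05.

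Native genes higher and lower in growth plate numbered 721 and 441 at 2-fold or more and 56 and 11 at 8-fold or more, and genes apart at both days 117 and 5, by construction. Every probe set as a feature gave 595, 167 and 55, from more features. The 60th percentile floor gave 107 higher and 9 at both days, a higher floor shrinking ratios. At both days the filter on all 6 arrays gave 9, and the mean of probe sets 11.

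The correlations of the culture response between tissues and of the tissue difference between stages moved by less than 0.1 under all 9 alternatives run for them; that of the change from day 10 to day 20 was not rerun. Of gene list medians 640 stayed the same, 67 moved and 1 was counted as reversed because it lost its sign. That was the growth plate signalling median for day, 0 with no filter against 0.48 as reported. With no filter this list grew from 9 genes to 13, by genes above the floor on fewer than 2 arrays. The cause of the 67 moves was not tested. Of values for named genes with a test, 505 stayed the same, 147 became called and 13 were no longer called; of native ratios, 134 stayed the same and 32 moved by more than 0.5. Signals near the floor of 36.1 limit the folds given as lower bounds.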

Other observations

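For named and listed genes with more than 1 probe set above the floor on at least 2 arrays, the others were compared with the probe set used. There were 148 others. Where the probe set used differed by at least 2-fold, the other went the opposite way by at least 2-fold in 0 of 41 for tissue, 0 of 29 for culture, 0 of 40 for day and 1 of 63 for the native difference, and had the same sign in 39, 27, 36 and 53. Where the probe set used differed by less, some others differed by more than 2-fold. That gene, FNTA, a subunit of farnesyltransferase, had native log2 differences of 2.09 and -1.27 on its probe sets, and was singled out after its values were seen. A tissue-by-culture limma fit, chosen after the data were seen, called 0 genes, with 1082 genes at an unadjusted p under 0.05 for the articular response, 283 for the growth plate response and 471 for their difference.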
